A study of Mus musculus with 4 samples.

How the data were processed

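Total RNA from mouse liver was labelled with Cy3-streptavidin and hybridised to single-colour Illumina bead arrays, per the labels, with 2 arrays of control mice and 2 of liver-specific ROCK1 KO mice. RNA was extracted with a column kit and its quality was examined on a Bioanalyser, per the labels' protocols. The deposited intensities are bead summary values per probe on a linear scale, and per the file headers they carry no detection p-values. Their lowest value lies far above 0 on each array, so no background had been subtracted. The authors' deposited log2 values of the same arrays have the same order of probes within each array as the intensities (rank correlation 1). They share the same lowest and highest value over the 4 arrays and nearly the same median, close to what quantile normalisation gives. They lie above the log2 mean distribution of these arrays by a median of 0.19. Their medians were 7.632, 7.631, 7.629 and 7.628, no gene centring was found, and what set their reference distribution is not given in the sources used here. Scanner software, slide and scan date are likewise not given in the sources used here.

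The plan made before the data were examined was background correction from detection p-values with limma's neqc and a detection filter. For a table without detection p-values, the plan named quantile normalisation of the intensities, an offset of 16, log2, and no detection filter, and that was used. A difference is thus on the log2(intensity + 16) scale with background left in, which makes differences of dim probes smaller than those of the transcripts. Tests used limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) without a block, with Benjamini-Hochberg adjustment over all 25697 probes, and a probe is called at an adjusted p under 0.05. These p-values are two-sided. In simulated arrays with the spread and probe means of this comparison (25697 probes, 200 changed in each of 10 runs), the fit recovered 20.4% of 1.5-fold, 89.1% of 2-fold and 100% of 4-fold changes, and 5.75% of its calls were false. The changed probes were drawn only from those with a mean above the background limit given below. No other difference shared by the arrays of a group was simulated, and the data gave 2060 called probes. These shares may therefore not hold for the data.

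Gene symbols came from the platform annotation, and 23962 probes were matched through their gene identifiers to a RefSeq table of assembly GRCm38.p6, used for names and gene order only, with 0 symbols changed. Of all probes 23978 had 1 symbol, 0 had several and 1719 had none, and those with a symbol covered 16593 genes. A gene was represented by its brightest probe over the 4 arrays, and where another of its probes above background on at least 2 arrays differed from it by 0.5 log2 units or more this is stated. A limit chosen after the data were seen called a probe above background over a log2 value of 7.86, which is 3 SD above the mode of the distribution. Where a group had no array above that limit, the change is a bound: the bright group's mean was set against the dim group's mean, with each dim array taken at no less than the lowest value above the limit. A probe at 60000 or more on both arrays of a group was treated as near saturation, and its fold change is likewise a bound.

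Named genes followed a rule fixed before the data were examined: Rock1 and Rock2, the 12 largest called rises and 12 largest called falls without overlap of the arrays, called members and up to 4 members with the smallest p in each list, and 13 fixed genes (Srebf1, Fasn, Acaca, Scd1, Acly, Cpt1a, Cyp7a1, G6pc, Pck1, Alb, Xist, Ddx3y and Eif2s3y). Among the list members that this rule covers, the examples printed were picked after their values were seen, with preference for calls kept when any 1 array was left out. The 29 gene lists held 836 genes fixed in advance, of which 737 were measured, and the result of 1 list is not reported here. Lists were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Alternatives covered the offset, the background correction, the normalisation, the authors' values, filters on dim probes, the variance model, the replicate number as a block, each array left out, the threshold, the probe per gene and the set test. Figures were drawn with matplotlib 3.10.9.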

Results

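RNA from the livers of control mice and of mice with a liver-specific knockout (KO) of ROCK1, a kinase that acts on actomyosin, was hybridised to single-colour Illumina bead arrays, with 2 arrays per group. All mice had eaten normal chow for 16 weeks. Each array gave an intensity for 25697 probes. The median intensity was 144.9 and 136.9 on the control arrays and 203.4 and 206.3 on the KO arrays, and the most frequent intensity, that of the background, was 127.8 and 124.1 against 180.0 and 180.8. After normalisation the Pearson correlation across probes, which are not independent replicates, was 0.991 within each group and 0.975 to 0.976 between groups. The comparison addresses how hepatic gene expression differs between the genotypes. The labels do not say whether the arrays came from separate animals, so the p-values measure only the spread between these arrays, and the number of arrays limits the precision.

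Rock1, the targeted gene, was read by 1 probe (ILMN_2742675). Its normalised log2 intensity was 8.51 and 8.51 on the control arrays and 8.06 and 7.91 on the KO arrays, a difference of -0.53 (SE 0.12, 1.44-fold lower, limma adjusted p = 0.0181). Before normalisation its intensities were 341.4 and 263.4 in control and 290.0 and 261.1 in KO, so the groups overlapped on that scale. Those intensities include the background, whose most frequent value was 127.8 and 124.1 in control and 180.0 and 180.8 in KO. After normexp background correction the difference was -0.83 with quantile normalisation and -0.79 with 75th percentile scaling. The call was lost without control replicate 1, control replicate 2 or KO replicate 2 (adjusted p of 0.0911, 0.0995 and 0.0961) and held without KO replicate 1 (0.0221). Which part of the gene was deleted is not given in the sources used here, and a probe outside that part could miss the deletion.

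**Figure D1:**
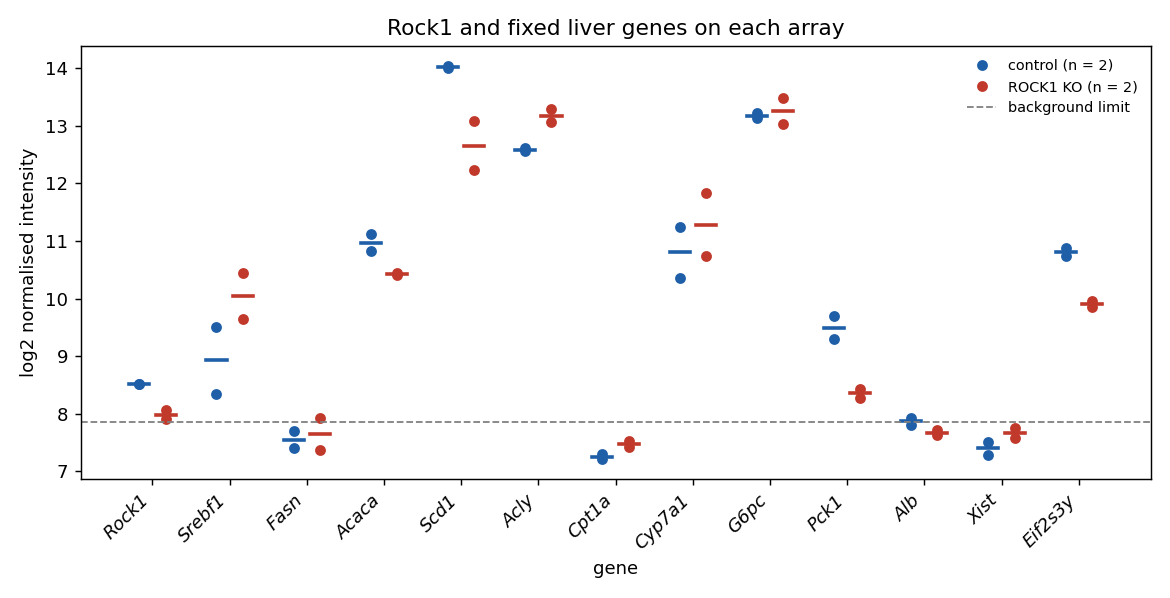
Normalised log2 intensity (vertical axis) of Rock1 and of the fixed liver genes (horizontal axis) on each of the 2 control and 2 ROCK1 KO arrays; points are arrays, short lines are group means, and the dashed line at 7.86 is the background limit. Scd1, Pck1 and Eif2s3y lay lower on both KO arrays, Acly lay higher, and Fasn, Cpt1a and Xist lay near or below the limit.

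Among genes with a symbol, each read by its brightest probe, the largest called rise was that of Selenbp2, a selenium-binding protein gene, from 9.70 ± 0.41 in control to 12.90 ± 0.50 in KO (log2, SD, n = 2; difference 3.20, SE 0.24, limma adjusted p = 4.54e-05). Them7 rose by 2.69, and Nnmt, which encodes nicotinamide N-methyltransferase, rose by 2.64, with 1.48 on its other bright probe. Dct, the dopachrome tautomerase gene of melanin synthesis, rose by 2.58, Mug2, a murinoglobulin protease inhibitor gene, by 1.96, and Anpep, an aminopeptidase gene, by 1.87. Rmdn3 rose by 2.47, with 0.52 on its other bright probe. The fatty acid omega-hydroxylase genes Cyp4a12b and Cyp4a14 rose by 2.49 and 1.98. Gdpd3, H2-Bl and Gm4956 were not above background on any control array and were at least 4.56-fold, 4.12-fold and 3.31-fold higher in KO. Without control replicate 2 the calls of Cyp4a14 (1.15, adjusted p = 0.0542) and Gdpd3 (adjusted p = 0.0504) were lost, and without KO replicate 2 Gdpd3 read 1.71. With a robust variance model the calls of Gdpd3, Dct, Cyp4a12b and Cyp4a14 were lost (adjusted p of 0.301, 0.0518, 0.133 and 0.366).

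Among the same genes the largest called fall was that of Serpina1e, an alpha-1-antitrypsin gene. It was near saturation on both control arrays (15.84 and 15.99) and read 13.02 and 9.91 on the KO arrays, at least 21.9-fold lower (limma adjusted p = 0.00220), and the log2 difference ran from -6.06 without KO replicate 1 to -2.98 without KO replicate 2. Serpina1a, of the same family, also fell (-1.82), and the probes of such close paralogues may bind each other's transcripts, which makes their values uncertain. The major histocompatibility genes H2-T10 (-3.05), H2-Ab1 (-2.26) and H2-D1 (-2.01) fell, as did Gm8909 (-2.84), and the other bright probes of H2-Ab1 read -1.29, -1.83 and -1.24. Hsd17b6, a steroid dehydrogenase gene, fell (-1.97), as did Cyp2c39 (-1.79), Apoh, which encodes a plasma apolipoprotein (-1.79), and Slc8b1, a mitochondrial sodium-calcium exchanger gene (-1.75). Slc25a30, a mitochondrial carrier gene, fell (-2.45) with KO arrays at 9.52 and 7.42. 4833439L19Rik fell (-1.74) on its brightest probe, while its other bright probes read -0.16 and -0.18. Without control replicate 2 the call of Slc25a30 was lost (adjusted p = 0.112), without KO replicate 2 it read -1.40, and without control replicate 1 the Cyp2c39 difference was -1.12. With a robust variance model the calls of Serpina1e, Slc25a30 and Cyp2c39 were lost (adjusted p of 0.303, 0.374 and 0.207).

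**Figure D2:**
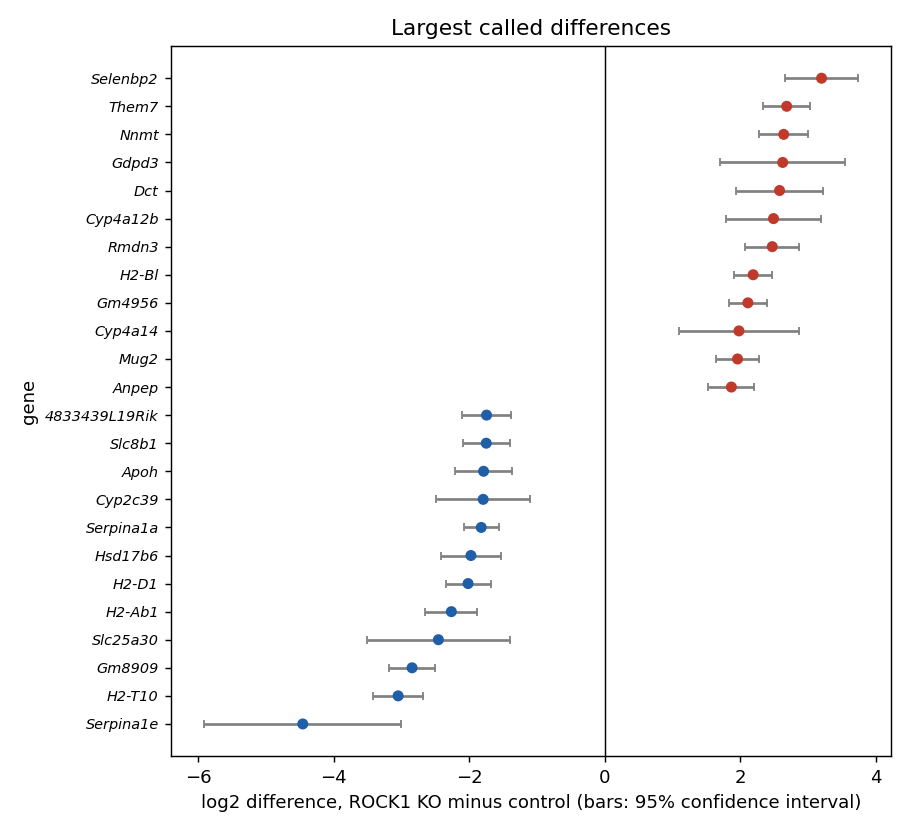
Log2 difference of ROCK1 KO minus control (horizontal axis) for the 12 genes with the largest called rise and the 12 with the largest called fall (vertical axis), from 2 arrays per group; bars are 95% confidence intervals of the limma fit. Differences run from -4.45 for Serpina1e to 3.20 for Selenbp2.

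Over all probes, 949 were called higher and 1111 lower in KO liver by limma, which is 8.02% of all probes, and of the 9493 probes above background on at least 2 arrays 1745 were called (18.4%). With 1 probe per gene, 697 genes were higher and 769 lower. By size, 547 probes were at least 1.5-fold higher and 779 at least 1.5-fold lower with no overlap of the arrays, where 51.9% of all probes showed no overlap against 33.3% by chance. These counts were 2128 and 2110 with normexp and quantile normalisation, and 3014 and 1641 with normexp and 75th percentile scaling, where more probes were higher than lower. Limma called 333 probes higher and 488 lower without control replicate 1, 294 and 506 without control replicate 2, and 599 higher without KO replicate 2.

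Of 19 measured genes of cholesterol synthesis and uptake, 7 rose, 2 fell and 10 were not called, and 10 rose and 3 fell when adjusted over the list alone. Mvd, a decarboxylase gene of the mevalonate pathway, rose by 1.23 and kept its call in all 4 leave-one-out fits. Sqle (squalene epoxidase) and Fdps (farnesyl diphosphate synthase) rose by 1.38 and 1.35, and the other bright Sqle probe, above background on 0 control arrays, was not called (adjusted p = 0.0523). Insig1, which restrains the processing of sterol-responsive transcription factors, fell (-1.40) on its brightest probe, with 0.16 and 0.35 on its others, and Idi1, an isomerase gene of the pathway, also fell (-0.82). As a set the list was not called (median 0.57, camera adjusted p = 0.0757). The calls of Sqle and Fdps were lost without either control array (highest adjusted p of 0.143 and 0.0750) and with a robust variance model (0.189 and 0.0645), their differences were 0.82 and 0.86 without KO replicate 1, and the calls of Insig1 and Sqle were lost with the mean of all probes of a gene (0.499 and 0.0658).

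Of 25 measured genes of de novo lipogenesis, 3 rose, 3 fell and 19 were not called, and 10 rose and 4 fell when adjusted over the list alone (median 0.27, camera adjusted p = 0.219). Scd1, the stearoyl-CoA desaturase gene of the liver, fell from 14.03 ± 0.02 to 12.65 ± 0.60 (log2, SD, n = 2; difference -1.38, SE 0.22, limma adjusted p = 0.00297). Me1, the malic enzyme gene, fell (-1.33) on its brightest probe and read 0.85 on its other, and its call was lost with the mean of its probes (0.692). Acly (ATP citrate lyase) rose by 0.59, a call lost in 3 of 4 leave-one-out fits, those without control replicate 1, control replicate 2 or KO replicate 1 (highest adjusted p = 0.119). Srebf1, the gene of a lipogenic transcription factor, read 1.12 (SE 0.33, adjusted p = 0.0623) and ran from 0.53 without control replicate 1 (adjusted p = 0.373) and 0.73 without KO replicate 2 (0.265) to 1.72 without control replicate 2 and 1.52 without KO replicate 1, where it was called (0.0206 and 0.0163). With all 4 arrays Srebf1 was called with the replicate block (1.69e-06) and with 75th percentile scaling alone (1.14, adjusted p = 5.59e-09) or after normexp (1.38, 0.000915), and its adjusted p was highest with a robust variance model (0.431). Its own SD in the main fit was 0.83 in control and 0.56 in KO. The eBayes step also draws variance from other probes, so these adjusted p-values do not measure the spread of Srebf1 alone. The block rests on replicate numbers with no stated pairing. Acaca, the acetyl-CoA carboxylase gene, read -0.54 (adjusted p = 0.0683) and was called with no intensity trend, a robust variance model, the replicate block, 75th percentile scaling alone or after normexp, and both background filters (0.0218 to 0.0436). It was not called without any 1 array (highest adjusted p = 0.323). The Fasn probe was above background on 1 of 4 arrays and read 0.10, and -0.056 and -0.17 without control replicate 1 and KO replicate 2.

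Of 32 measured genes of fatty acid oxidation and ketogenesis, 1 rose, 4 fell and 27 were not called, and 2 rose and 5 fell when adjusted over the list alone (median 0.10, camera adjusted p = 0.945). The gene that rose was Cyp4a14, and Hadhb, a subunit gene of the mitochondrial trifunctional protein, fell (-1.23). Cpt1a, which governs mitochondrial fatty acid entry, was not above background on any array. Of 35 genes of lipid storage, uptake and secretion, 2 rose, 3 fell and 30 were not called, or 3 and 5 adjusted over the list alone (median 0.02, mean -0.04, camera direction down, adjusted p = 0.719). Fabp5, a fatty acid binding protein gene, was at least 1.64-fold lower, and Vldlr, a lipoprotein receptor gene, fell (-0.89), with -0.11 and -0.68 on its other bright probes. Tm6sf2 rose by 0.81.

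Of 20 measured genes of glucose and glycogen metabolism, 0 rose, 2 fell and 18 were not called, with the same counts adjusted over the list alone (median -0.0088, camera adjusted p = 0.688). Pck1, the phosphoenolpyruvate carboxykinase gene of gluconeogenesis, fell from 9.49 ± 0.29 to 8.35 ± 0.11 (log2, SD, n = 2; difference -1.14, SE 0.16, limma adjusted p = 0.00162), and the glucose-6-phosphate transporter gene Slc37a4 fell (-0.98). G6pc, the glucose-6-phosphatase gene, read 0.07 (SE 0.16, adjusted p = 0.837), and -0.15 without KO replicate 1. Of 23 genes of insulin, IGF and growth hormone signalling, 3 rose, 4 fell and 16 were not called, or 6 and 6 adjusted over the list alone (median -0.0097, camera adjusted p = 0.719). Irs1, an insulin receptor substrate gene, was at least 1.34-fold higher, Igfbp1 at least 1.46-fold lower, and Ptpn1, a phosphatase gene that acts on the insulin receptor, fell (-0.86). Of 17 genes of AMPK and the endocannabinoid system, 0 rose, 1 fell and 16 were not called, or 0 and 2 adjusted over the list alone (median -0.04, camera adjusted p = 0.579), and the gene that fell was the kinase gene Sik1 (at least 1.19-fold lower).

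No probe was named Rock2. Of 27 measured SRF/MRTF and YAP targets, 0 rose, 2 fell and 25 were not called, or 2 and 3 adjusted over the list alone (median -0.08, camera adjusted p = 0.688). Actb (beta-actin) fell (-0.66) on its brightest probe, while its other bright probes read -0.96, -0.17, 0.20 and -1.06, and Vcl (vinculin) also fell (-0.61). The call of Actb was lost without control replicate 2 or KO replicate 2 (highest adjusted p = 0.111) and with the mean of its probes (0.167), and that of Vcl without control replicate 1, control replicate 2 or KO replicate 2 (0.208).

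Of 25 measured genes of bile acid synthesis and transport, 1 rose, 7 fell and 17 were not called, or 2 and 9 adjusted over the list alone (median -0.01, camera adjusted p = 0.137). Abcc2, a canalicular exporter gene, rose by 1.13 on its brightest probe and read 0.14 on its other. Abcb4, the phospholipid exporter gene, fell (-0.77), a call lost without control replicate 1 (adjusted p = 0.0719), and Baat, a bile acid conjugation gene, fell (-0.84), a call lost without either control array (0.0781 at most). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, read 0.48 (SE 0.33, adjusted p = 0.440), turned to -0.053 without KO replicate 1 (0.953) and was called at 1.03 without KO replicate 2 (0.0479). Of 44 genes of xenobiotic metabolism, 9 rose, 5 fell and 30 were not called, or 11 and 10 adjusted over the list alone (median 0.06, camera adjusted p = 0.579). The glutathione transferase gene Gstm2 rose by 1.84, the cytochrome P450 gene Cyp2a5 rose by 1.13 (0.63 on 1 of its other bright probes and at least 1.36 on the rest), and Cyp2c55 was at least 1.76-fold higher, all in families with close paralogues, so these values are uncertain.

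Of 22 measured NRF2 and antioxidant genes, 1 rose, 4 fell and 17 were not called, or 1 and 5 adjusted over the list alone (median 0.02, mean -0.14, camera direction down, adjusted p = 0.579). Gclc, the catalytic subunit gene of glutathione synthesis, fell (-1.10), Txn1 (thioredoxin) fell (-1.18), and Txnrd1 (thioredoxin reductase) was at least 1.83-fold lower. The call of Txn1 was lost with the mean of all its probes (0.138), of which only the brightest was above background on at least 2 arrays. Of 25 genes of ER stress and the amino acid response, 4 rose, 4 fell and 17 were not called, or 6 and 4 adjusted over the list alone (median 0.05, camera adjusted p = 0.579). Creld2 rose by 1.19, with 1.78 on its other bright probe, and Herpud1, of ER-associated degradation, by 1.04. Asns (asparagine synthetase) was at least 2.74-fold higher, and at least 1.30-fold on its other bright probe, a call of the brightest probe lost with a robust variance model (0.0863).

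Of 29 measured genes of the urea cycle and amino acid catabolism, 6 rose, 6 fell and 17 were not called, or 12 and 9 adjusted over the list alone (median 0.33, mean 0.0096, camera adjusted p = 0.688). Ass1 (argininosuccinate synthase) rose by 1.29, and Gnmt (glycine N-methyltransferase) by 0.88. Dmgdh (dimethylglycine dehydrogenase, -1.57), Ahcy (-1.29), Glul (glutamine synthetase, -1.14) and Tdo2 (tryptophan dioxygenase, -1.10) fell. Of 48 genes of oxidative phosphorylation, 4 rose, 7 fell and 37 were not called, or 11 and 8 adjusted over the list alone (median -0.0027, camera adjusted p = 0.774). The ATP synthase gene Atp5a1 (-1.41) and the complex I gene Ndufb9 (-1.02) fell, and Cycs (cytochrome c) fell (-0.99) on its brightest probe, with -0.16 on its other.

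Of 35 measured acute phase and inflammation genes, 2 rose, 4 fell and 29 were not called, or 2 and 6 adjusted over the list alone (median -0.13, camera adjusted p = 0.105). Hamp2, a hepcidin gene, rose by 1.69, a call lost without control replicate 2 (adjusted p = 0.0588) and with a robust variance model (0.0648), and Lbp, the lipopolysaccharide binding protein gene, fell (-0.96), a call lost without control replicate 1 (0.125). Of 36 interferon response genes, 4 rose, 9 fell and 23 were not called, or 4 and 10 adjusted over the list alone (median -0.11, camera adjusted p = 0.0513). Besides H2-Ab1 and H2-D1, the invariant chain gene Cd74 (-1.48), Igtp (-1.12) and the chemokine gene Cxcl9 (-1.44) fell, while H2-K1 rose by 0.95 on its brightest probe, and its other, above background on 0 KO arrays, was not called (at least 1.14-fold lower, adjusted p = 0.0599). Cxcl9 read -0.76 without control replicate 1, and its call was lost with a robust variance model (0.295) and, at the same difference, when all genes were tested by the mean of their probes (0.0507), where that of H2-K1 was lost too (0.110).

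Markers of cell types were measured beside these groups. Of 24 hepatocyte markers, 2 rose, 6 fell and 16 were not called, or 2 and 7 adjusted over the list alone (median -0.11, mean -0.38). The median was -0.056 without control replicate 2, -0.50 with normexp and 75th percentile scaling and -0.52 with 75th percentile scaling alone. The 75th percentile of intensity was 344.7 and 266.2 in control and 401.9 and 397.5 in KO. Scaling by it alone thus lowers the KO arrays more, and the larger fall may come from the scaling. The hepatocyte list was the only called list among 29 (camera adjusted p = 0.00445), and it was not called with an estimated correlation (adjusted p = 0.863), with fry (0.199) or over genes above background on at least 2 arrays (0.128). Serpina1a, Serpina1c (-1.53), Apoh, Rbp4 (-1.21) and Fgl1 (-1.17) fell. The transcription factor gene Cebpa rose by 1.02 and the apolipoprotein gene Apoe by 0.36, a call lost without control replicate 1, control replicate 2 or KO replicate 1 (highest adjusted p = 0.117) and with 75th percentile scaling alone (0.886). The Alb probe was above background on 1 of 4 arrays and so did not report this abundant transcript. Of 21 macrophage markers, 0 rose, 3 fell and 18 were not called, or 0 and 4 adjusted over the list alone (median -0.10, camera adjusted p = 0.0513), with the scavenger receptor gene Cd163 lower (-1.32). Of 23 endothelial markers, 0 rose, 2 fell and 21 were not called, or 1 and 2 adjusted over the list alone (median -0.14, camera adjusted p = 0.0934), with the sinusoidal lectin gene Clec4g lower (-0.94).

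Of 26 stellate cell and matrix markers, 0 rose, 3 fell and 23 were not called, with the same counts adjusted over the list alone (median -0.02, camera adjusted p = 0.579), and Colec10 fell (-0.66), a call lost without control replicate 1 (0.0960). Of 15 cholangiocyte markers, 2 rose, 0 fell and 13 were not called, or 3 and 0 adjusted over the list alone (median 0.07, camera adjusted p = 0.579). Of 27 lymphocyte and neutrophil markers, 1 rose, 1 fell and 25 were not called, on either adjustment, also adjusted over the list alone (median -0.04, camera adjusted p = 0.579), and 0 were above background on at least 2 arrays. Of 8 blood erythroid markers, 1 rose, 0 fell and 7 were not called, also adjusted over the list alone (median -0.0052, mean 0.11, camera direction up, adjusted p = 0.719). Of 23 pancreas, fat and muscle markers, 0 rose, 1 fell and 22 were not called, also adjusted over the list alone (median 0.02, camera adjusted p = 0.823), the amylase gene Amy2a5 being lower (-1.16).

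Of 25 measured cell cycle genes, 1 rose, 2 fell and 22 were not called, or 3 and 2 adjusted over the list alone (median 0.10, camera adjusted p = 0.579). Ccnd1 (cyclin D1) fell (-1.01), with -0.31 and -0.85 on its other bright probes, a call lost without control replicate 2 (adjusted p = 0.0956). Of 20 circadian clock genes, 2 rose, 1 fell and 17 were not called, or 3 and 4 adjusted over the list alone (median 0.07, camera adjusted p = 0.823). Nr1d1, a clock repressor gene, rose by 0.85, a call lost without control replicate 1 (0.124) and with the mean of its probes (0.0758).

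Of 19 measured male-biased liver genes, 5 rose, 3 fell and 11 were not called, or 7 and 6 adjusted over the list alone (median 0.08, camera adjusted p = 0.688). Besides Cyp4a12b, Cyp4a12a rose by 1.01, while Serpina1e, also in this list, was at least 21.9-fold lower. The Y-linked gene Eif2s3y fell from 10.80 ± 0.10 to 9.91 ± 0.07 (log2, SD, n = 2; difference -0.90, limma adjusted p = 0.00522), a call lost without control replicate 1 (0.0621). It was above background on all 4 arrays, and Xist, which is expressed in females, was above background on none. No probe was named Ddx3y. Of 15 female-biased genes, 0 rose, 0 fell and 15 were not called, also adjusted over the list alone (median -0.0074, mean 0.01, camera direction up, adjusted p = 0.821). With an estimated correlation no list was called, and the lowest adjusted p was 0.863.

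**Figure D3:**
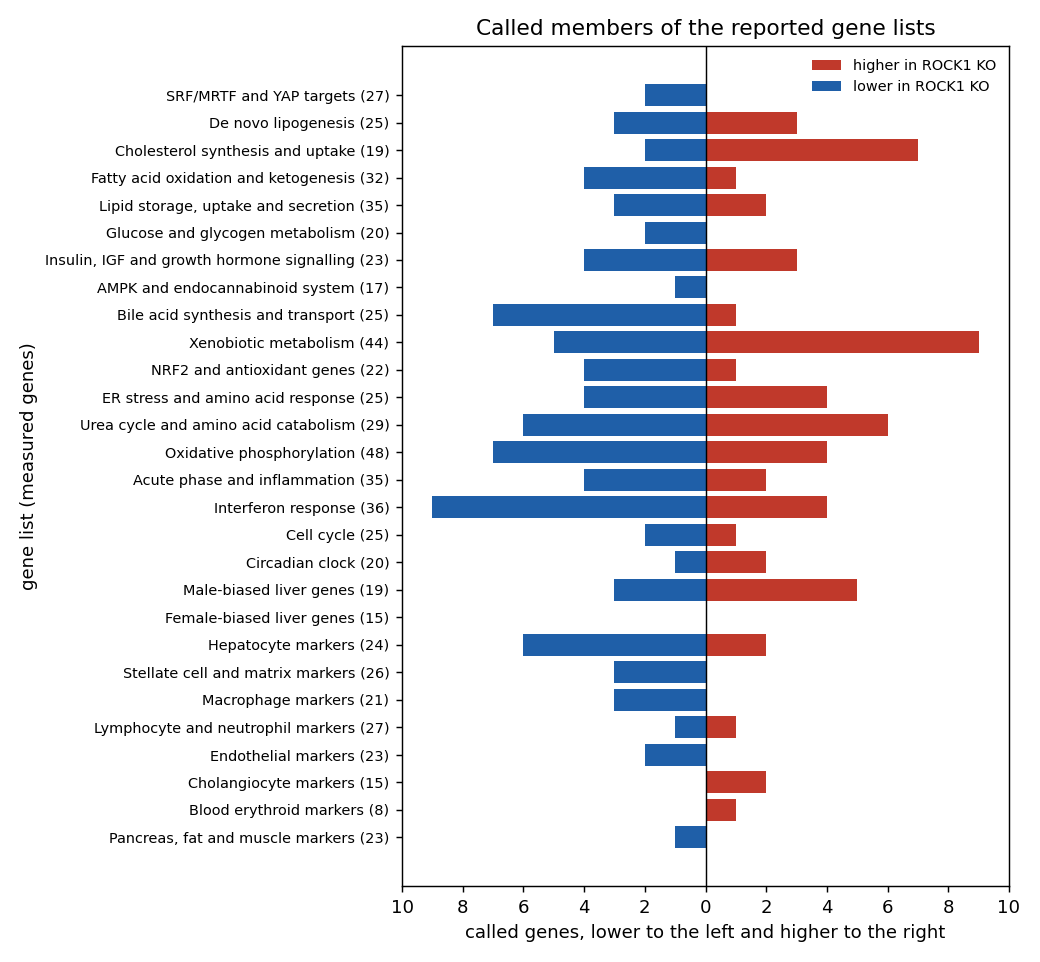
Number of called genes per reported list, lower in ROCK1 KO to the left and higher to the right (horizontal axis), with the number of measured genes in brackets after each list name (vertical axis). Cholesterol synthesis and uptake had 7 higher and 2 lower, bile acid synthesis and transport 1 higher and 7 lower, and hepatocyte markers 2 higher and 6 lower.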

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

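The background filters, normexp (fitted on the intensities, as no detection p-values were in the table), scaling to the 75th percentile, and removal of H2 genes and genes with disagreeing probes were chosen after the data were seen. Detection filters, normexp from detection p-values and a slide block were not run. Of 176 called genes that the naming rule covers or the text names, 155 kept their call and direction under every other normalisation, 77 in every leave-one-out fit and 64 under every alternative that tested them. Besides the 75th percentile scalings, the other normalisations rest on the order of probes within each array, as the main one does. Those normalisations are thus weak checks. Leaving out 1 array leaves a lone array in its group, assumed to vary like the other group. Under these fits the Rock1 difference ran from -0.61 to -0.46, higher probes from 294 to 799, lower probes from 488 to 880, and called lists from 1 to 5. Without KO replicate 1 Cyp7a1 turned to -0.053 and G6pc to -0.15, and Fasn turned to -0.056 without control replicate 1 and -0.17 without KO replicate 2, with ranges of -0.053 to 1.03 for Cyp7a1, -0.15 to 0.30 for G6pc and -0.17 to 0.38 for Fasn, and none of the 3 was called in the full fit. With the mean of all probes of a gene Mgst1, named after its values were seen, turned from -0.20 to 2.27 and Ndufa5 from 0.70 to -0.22, as their probes disagree. Normexp with quantile normalisation enlarged the differences of 37 of the 170 calls it kept by over 1.5 times, and took Rock1 to -0.83. The causes, among them the lower power of fits with fewer arrays, were not tested. The replicate block raised the calls to 1440 higher and 1480 lower and the called lists to 4. The replicate numbers share no stated pairing, and the deviations of same-numbered arrays correlated at -0.0571 over all probes, so the numbers are not read as pairs. The block left Rock1 at -0.53. A threshold of 0.10 gave 1598 higher and 1602 lower probes and 5 lists. Without H2 genes and genes with disagreeing probes 906 higher and 1024 lower probes were called. Counts by size fell to 122 higher and 221 lower with a 2-fold minimum. They rose to 2128 and 2110 with normexp and quantile normalisation, and to 3014 and 1641 with normexp and 75th percentile scaling, since subtraction enlarges the folds of dim probes. That last scaling shifted the median of all probes by 0.11. It called 7 lists, 75th percentile scaling alone called 10, and a filter for probes above background on all 4 arrays called 2. Camera with an estimated correlation, fry, and the filter for at least 2 arrays called 0 lists. Signal over background limits the readout beside the number of arrays, since 15342 probes were below background on all 4 arrays.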

Other observations

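The tests of the normexp correction, the Rock1 neighbourhood and chromosome, the splits of the arrays and the H2 genes were chosen after the result was seen, as were the unnamed probe and Wdr46, H2-T23, H2-Q7, H2-DMa, H2-DMb1 and Mgst1. Some of the largest differences lay outside the named genes. The unnamed probe ILMN_2970494 rose from 9.38 ± 0.01 to 14.88 ± 0.16 (log2, SD, n = 2; limma adjusted p = 9.15e-09). Wdr46 was not above background on any control array and was at least 2.31-fold and 2.19-fold higher on its probes. Among genes named H2, H2-T23 rose by 1.56 on its brightest probe and was at least 5.68-fold higher on its other, H2-Q7 rose by 1.06, while H2-T10, H2-D1 and H2-Ab1 fell. The Y-linked gene Kdm5d was at least 1.33-fold lower, beside the fall of Eif2s3y, and its call was lost without control replicate 2 or KO replicate 1 (highest adjusted p = 0.128).

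The first pattern is the number of called probes, 2060 between the genotypes against at most 0 in the other splits of the 4 arrays. At an unadjusted limma p under 0.05 the counts were 5644 against 317 and 326. In the other splits each group holds 1 control and 1 KO array. Any difference shared by the arrays of a genotype widens the spread within such groups, so 0 calls there is not a fair null for 2060. Only 1 of the 3 splits, the real one, gave as many, and 3 splits are too few for a share under 0.05. The higher background of the KO arrays stays open. After normexp correction with quantile normalisation 92.7% of the called probes kept their call and direction, as predicted if it were not the whole source. That does not decide it, since quantile normalisation uses only the order of probes within an array, which normexp leaves as it was. With normexp and 75th percentile scaling, which uses the values, 90.7% kept both. Of its calls 52.9% were higher, against 46.1% in the main fit. DNA carried along with the targeted allele is argued against as the whole source where it acts only on genes of its own chromosome. Of the 1466 called genes 98.3% lie on other chromosomes than Rock1 (exact 95% lower bound 97.5%). An effect of such DNA on genes of other chromosomes stays open, since their location cannot exclude it. Separate processing of the control and KO arrays stays open and met its prediction: among 15342 probes below background on all 4 arrays, 43.6% showed no overlap of the genotypes, 15.2 percentage points more than the larger mixed split and, as the shares of the 3 splits sum to 100%, 10.3 points over chance, or 5.70 points among the 9341 dimmest. For the genes near Rock1 such DNA stays open, since 8% of the 50 measured genes nearest to Rock1 were called (4 genes, exact 95% interval 2.22% to 19.2%) against 8.84% of all genes. Slide and scan date are not given in the sources used here, so processing and genotype cannot be told apart, and loss of ROCK1 itself stays open as untested.

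The second pattern is that bright probes of the same gene disagreed. In 86 of 1612 genes with several bright probes (5.33%) the genotype differences of the probes lay over 1 log2 unit apart. For Mgst1 they were 4.74 and -0.20, and in 7 of the genes, Ndufa5 (0.70 and -1.13) among them, probes were called in opposite directions. Array noise is argued against, since the splits that mix genotypes gave at most 1 such gene, and so is saturation, since in 90.7% of the 86 genes every bright probe had a mean under 14, though not for Mgst1, whose -0.20 probe had means of 15.68 and 15.48 and where saturation stays open. A sequence variant under a single probe may be a candidate explanation: in 20 of 33 disagreeing genes with 3 or more bright probes (60.6%, exact 95% interval 42.1% to 77.1%) 1 probe stood apart from others within 0.5, which does not decide it, and alternative transcripts would give the same.

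The third pattern is that 9 H2 genes were called higher and 5 lower among 35. Several lay near background. H2-Aa, H2-Eb1, H2-M10.1, H2-M10.5 and H2-Q1 were above background on 0 control arrays and at least 1.01-fold to 1.29-fold higher. H2-DMa and H2-DMb1 were above background on 0 KO arrays and at least 1.37-fold and 1.48-fold lower. A changed share of antigen-presenting cells is argued against as the whole source for the class I genes, since among those clearly above background 4 were called higher and 2 lower, but it stays open for the falls of the class II genes H2-Ab1, H2-DMa and H2-DMb1 and of Cd74, beside which the macrophage markers did not pass (camera adjusted p = 0.0513). Without control replicate 1 the calls of H2-DMa and H2-DMb1 were lost (adjusted p of 0.0638 and 0.0601). The class II genes H2-Aa and H2-Eb1 were above background on no control array and were called higher (at least 1.08-fold and 1.07-fold), which lies too near background to exclude it. Those calls were lost without control replicate 2 or KO replicate 2, and for H2-Eb1 also without control replicate 1 (highest adjusted p of 0.133 and 0.107). A change of most genes in the chromosomal stretch is also argued against. Of the 423 other genes between the outermost H2 genes 10.6% were called, against 8.84% of all genes, and among bright genes 18.8% against 18.3%. These shares cannot exclude a stretch that differs between the genotypes but alters only some of its genes. Different H2 alleles in the control and KO mice stay open: among called probes of at least 2-fold, 2 of 10 H2 probes were above background in only 1 genotype against 31 of 329 others (one-sided Fisher's exact p = 0.253). Over all probes above background on at least 2 arrays this held for 8 of 20 H2 probes, 5 in KO and 3 in control, against 668 of 9473 others, as different alleles would give. Among the 8, the probes of H2-Eb1, H2-M10.1, H2-Q1, H2-DMa and H2-DMb1 and the dimmer H2-K1 probe lay near the limit (bounds of 1.07-fold to 1.48-fold). Any change of H2 genes in both directions would raise the share of 8 in 20 too, so that share does not decide. The genetic background of the mice is not given in the sources used here, regulation of single H2 genes would look alike, and H2 probes may bind each other's transcripts.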
